A study of Mus musculus with 2 samples.

How the data were processed

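H3K4me1, the histone H3 lysine 4 monomethylation that marks enhancers and the flanks of promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole lung of mouse embryos at 15.5 days of gestation, strain B6NCrl, with both sexes pooled. There was 1 group of 2 biological replicates. Per the labels, replicate 1 was pooled from the lungs of 78 embryos and replicate 2 from those of 62. With no second tissue, age or treatment in the design, the comparisons were between the replicates, between parts of the genome and between gene lists.

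The authors deposited 4 peak lists on mm10, which is GRCm38. Per the file headers and readmes, replicate 1 was called against 1 control alignment, and replicate 2 and the list from both replicates' pooled alignments were called against 2 control alignments. The fourth list, called the replicated list here, holds the pooled peaks that were kept after comparison with the replicates' own peaks. All 124795 of its rows were found unchanged in the pooled list. The lists of both replicates touched 84.2% of them, 1 list touched 15.1% and neither touched 0.639%. Overlap with these lists was thus not required of every row. The peak caller, aligner, their versions and the threshold are not given in the sources used here. Each deposited peak carries a display score, a fold of ChIP over control, a −log10 p-value and a −log10 q-value. These scores, folds and p-values are the authors' own, were made within each list, and were used only to rank or filter peaks within a list. The lists hold no read counts, so the sequencing depth is unknown. The confidence intervals of shared peaks given in the report treat peaks as independent draws and say nothing of depth. No peak ran past the end of its chromosome in the reference. Peaks on chromosomes 1 to 19 and X were used, which left out 1 peak on an unplaced X scaffold in each of the pooled list and the list of replicate 2.

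Peaks were compared as intervals. A peak was called shared when the other replicate's peaks covered at least 50% of its length, and chance was measured with 100 random circular shifts of the other list along each chromosome. The test of unshared peaks within 1 kb of the other list used 20 such shifts. Genes came from GENCODE release M21, with 1 transcription start site (TSS) for each of 21728 protein-coding genes, at the 5′ end of the annotated gene. Bases were assigned in the order promoter (within 1 kb of a TSS), exon, intron and intergenic. The TSS profile gives the share of TSSs covered by a peak at each distance. The distance of 2 kb in its ratio of flank to TSS coverage was chosen before the profile was computed but was not part of the design fixed before the data were examined. It was changed to 1 kb for a time after the profile had been seen and then set back, and the ratio at 1 kb is given as an added alternative.

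For each gene the share of the 50 kb on each side of its TSS lying under peaks was computed and ranked among all protein-coding genes in each replicate. Each of 19 gene lists was tested on its mean percentile with a two-sided permutation test against 100000 random lists of the same size matched on gene length. Benjamini-Hochberg adjustment ran over the 19 lists, and a call needed an adjusted p below 0.05 in both replicates. The smallest p that the permutations can give is 2.00e-05. A gene was called highly covered when it lay in the top 10% in both replicates, and uncovered when no peak of the replicated list lay in its window. Differences between lists were tested by permuting membership 100000 times, two-sided and without matching. Benjamini-Hochberg adjustment ran over the 18 pairs of lung and other-organ lists. For the Hox lists thinned to 4 genes each, all 70 splits were enumerated. These tests run over genes, which are not replicates of animals, and neighbouring genes share windows. The lists, motifs, the tests of the 5 comparisons and the rule for named genes were fixed before the data were examined. The pairs of lists that were set against each other, the test of a list's rank between the replicates, the tests of gene families and the alternatives named as added were chosen later. The rule named 25 lung and other-organ genes, the 3 members of each list with the highest coverage, the lowest member of each lung list, and the 10 genes with the highest coverage in the genome, leaving out any within 200 kb of a higher one.

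Occurrences of 10 short consensus motifs on either strand were counted in peaks and in 1 region per peak of the same width and chromosome, free of peaks and of unknown bases, with GC content within 2 percentage points. As a second control, 20000 peaks were shuffled with all dinucleotide counts kept. Values of the replicates are given as mean ± SD over their own lists (n = 2).

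The code was tested on simulated data. For the gene list test, 3.50% of 400 random lists of 25 genes had a p below 0.05, and lists drawn from 200 genes raised by 0.5 SD or 1 SD were recovered in 79.0% and 100.0% of 100 draws, with 21728 genes in each step. Simulated values were independent between genes and lists were drawn at random. These rates therefore do not cover lists of clustered genes that share windows. Covered lengths and motif counts equalled those from a second counter, and no shuffle changed a dinucleotide count. Alternatives covered the overlap rule, stricter and stronger peaks, the pooled list, each replicate alone, other windows, other matching and thinning of clustered genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.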

Results

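H3K4me1 peaks from whole embryonic mouse lung at 15.5 days were analysed in 2 biological replicates. Replicate 1 had 195749 peaks over 93.1 Mb, or 3.54% of chromosomes 1 to 19 and X, with a median width of 326 bp. Replicate 2 had 171380 peaks over 81.8 Mb, or 3.11%, with a median width of 333 bp. The replicated list held 124795 peaks over 94.5 Mb with a median width of 557 bp, and both replicates touched 84.2% of them. Sequencing depth is unknown, since the lists give no read counts.

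The first comparison asked how far the replicates' peaks coincided. The strongest regions were held by both. The peak with the highest fold in the replicated list, 10.2 by the authors' value, lay in an intron of Smad6, an inhibitor of BMP signalling, on chromosome 9 from 63978767 to 63986699 (GRCm38). Replicate 1 covered 94.7% of it and replicate 2 covered 84.6%. The next highest lay in an intron where Thra and Nr1d1 overlap, with a fold of 9.32, in an intron of Foxp4, a forkhead factor of lung epithelium, with 8.86, in an intron of the clock gene Per1, with 8.74, and at the Dedd2 promoter, with 8.64. The longest region covered 16046 bp of a Lasp1 intron on chromosome 11 from 97803645 to 97819690. Regions in introns of Sept9, Arhgef17, Tns1 and Pmepa1 followed, at 15555, 14527, 14331 and 13332 bp, and each replicate covered at least 89.9% of each of these 5 longest regions.

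Across all peaks, replicate 2 shared 52.0% of the peaks of replicate 1 (95% exact binomial interval 51.8 to 52.2) and replicate 1 shared 62.7% of those of replicate 2 (62.5 to 62.9). Random shifts gave 3.23% and 3.74%, which is 16.1 and 16.8 times less. The share rose with the authors' fold, from 33.5% in the lowest 10% of the list of replicate 1 to 91.9% in the highest 10%, and from 41.6% to 96.4% in replicate 2. Some strong peaks were still held by 1 replicate alone. In replicate 1 these lay in introns of Cnih1, Ahctf1 and Ubtf, with folds of 6.87, 6.34 and 6.22. In replicate 2 they lay at the promoter of Wt1, a mesothelial transcription factor, on chromosome 2 from 105126259 to 105126663, and in introns of Pik3ca and Rtn4rl1, each with a fold of 5.04. A replicated peak from 105126761 to 105128190 closely followed the Wt1 peak, and whether both belong to 1 region was not tested. For replicate 1 the share was 36.7% with a reciprocal overlap of 50% and 63.6% with any overlap. With both lists limited to a −log10 q of at least 5, as planned, it was 48.8%, and with replicate 1 alone so limited against the whole other list, chosen after seeing the data, it was 82.0%.

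**Figure D1:**
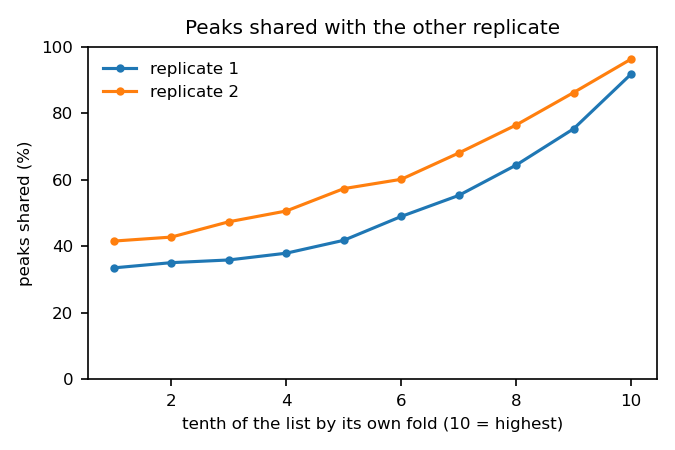
Share of each replicate's peaks (y axis, %) at least 50% covered by the other replicate, by the authors' fold, in steps of 10% of the list (x axis, 10 the highest). Each point is 10% of 1 replicate's list, and the lines run from 33.5% to 91.9% in replicate 1 and from 41.6% to 96.4% in replicate 2.

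The second comparison placed the mark relative to genes. Promoters held 9.43% of the replicated peak length in 1.60% of the genome, a 5.89-fold excess, with 5.61 ± 0.397 (SD, n = 2) from the replicates' own lists. Introns held the most, 54.3% of the length, at 1.502 ± 0.0153 times their share of the genome, exons were at 1.79 ± 0.103 times and intergenic sequence was at 0.521 ± 0.00731 times. Each of these departures from 1 was larger than the spread between the replicates. The densest 100 kb window lay in Nfib, a nuclear factor I gene needed for lung maturation, on chromosome 4 from 82400001 to 82500000, with 69.5% of its length under replicated peaks. Windows over Tns1 on chromosome 1, over Lyl1, G430095P16Rik and Nfix on chromosome 8, over Ncor2 on chromosome 5 and over Zfp608 on chromosome 18 had 69.0%, 68.3%, 64.4% and 61.0%. The median window had 0.722%, and 42.1% of the 26330 windows had no replicated peak.

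Around the TSS the mark formed a pair of shoulders. At the TSS itself 11.8% ± 0.944 of the 21728 TSSs were covered (SD, n = 2). Coverage was 21.9% ± 1.39 at 500 bp upstream, 30.3% ± 1.42 at 1000 bp downstream and 7.60% ± 0.595 at 5000 bp downstream. The ratio of coverage 2 kb away to coverage at the TSS was 1.14 ± 0.182 and so did not differ from 1 by more than the spread between the replicates. At 1 kb, a distance chosen after the profile was seen, it was 2.04 ± 0.281.

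**Figure D2:**
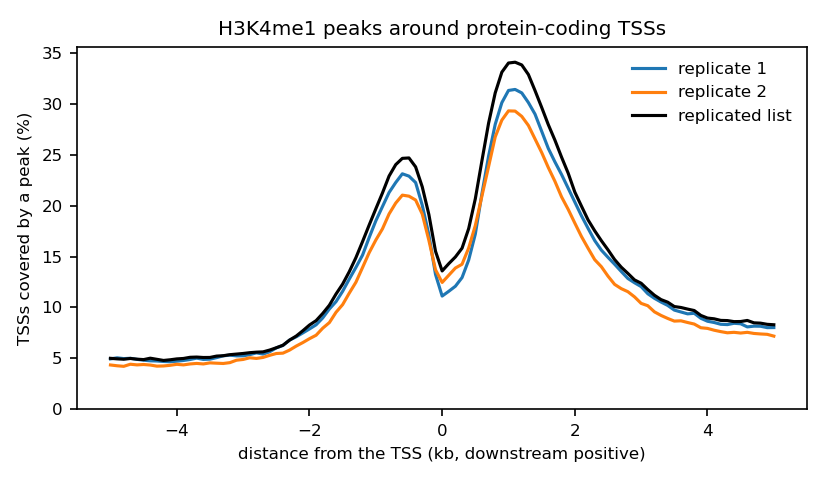
Share of protein-coding TSSs covered by a peak (y axis, %) against distance from the TSS (x axis, kb, downstream positive), for each replicate and the replicated list. The replicated list falls to 13.6% at the TSS between 24.7% upstream and 34.1% downstream.

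The third comparison set lists of lung cell types against lists of other organs. Among 19 lists, 7 ranked higher than random lists of like gene length in both replicates, 1 ranked lower and 11 were not called. The median gene had 4.02% ± 0.377 of its window under peaks (SD, n = 2), and the replicates' values had a Spearman correlation of 0.985 across genes, which are not independent replicates.

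Lung mesenchyme and smooth muscle genes had a mean percentile of 73.6 in replicate 1 and 73.7 in replicate 2 (adjusted p = 7.60e-05 and 9.50e-05, permutation test). Of its 37 members 13 were highly covered and none was uncovered. The highest were Tgfbi, an extracellular matrix protein, with 41.3% ± 3.55 of the window under peaks (SD, n = 2), Ptch1, the Hedgehog receptor, with 34.4% ± 1.25, and Dlk1 with 30.7% ± 0.728. Tbx4 and Foxf1, transcription factors of the lung mesenchyme, had 17.8% ± 0.764 and 17.6% ± 0.396, and Tbx5 had 14.7% ± 0.678. Foxf1 lies on chromosome 8 from 121084386 to 121088144, and the strongest replicated peak in its window lay 22767 bp downstream of its TSS, in an intron of Mthfsd and of the overlapping Gm20388. Fgf10, the growth factor that drives branching, was the lowest member at 0.702% ± 0.552, and from its RefSeq start, an alternative chosen after seeing the data, it had 2.24% ± 0.153.

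**Figure D3:**
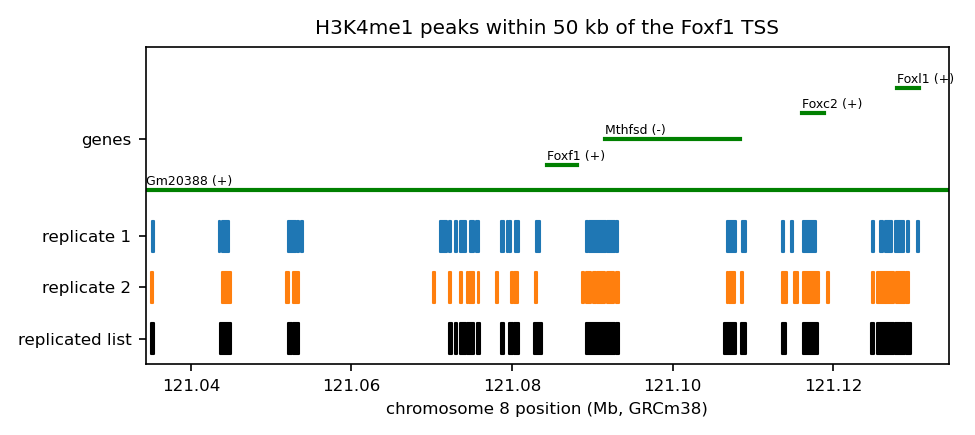
Peaks within 50 kb of the Foxf1 TSS on chromosome 8 (x axis, position in Mb, GRCm38). Blocks are peaks of replicate 1, replicate 2 and the replicated list, and green lines are protein-coding genes with their strand; 17.9% of the window lies under peaks of replicate 1 and 17.3% under those of replicate 2.

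Lung epithelium genes had mean percentiles of 71.3 and 69.4 (adjusted p = 7.60e-05 and 1.52e-04, permutation test), with 9 of 40 highly covered and 1 uncovered. Foxp4 had 32.4% ± 0.673 (SD, n = 2), Muc1, a membrane mucin, had 26.5% ± 0.227 and Fgfr2, the receptor of Fgf10, had 23.3% ± 2.45. The annotated start of Fgfr2 lies in Ctbp2, and from its RefSeq start the value was 30.8% ± 3.63. Sftpc, the surfactant protein C gene, had 16.5% ± 0.518, with the strongest peak of its window in an exon of Reep4. Foxa2 had 8.57% ± 1.83 and Sox9, a factor of the distal tips, had 7.49% ± 0.947. Nkx2-1, the lineage factor of lung epithelium, had 1.89% ± 0.0728, with 3 replicated peaks and the strongest in an exon of the gene itself. Lamp3 was the lowest, at 0.154% ± 0.218.

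Endothelial genes had mean percentiles of 66.9 in each replicate (adjusted p = 0.00937 and 0.00918, permutation test), with 5 of 25 highly covered. The call was lost with a window of 10 kb (higher permutation adjusted p = 0.0581). Eng, a TGF-beta co-receptor, had 29.4% ± 1.20 (SD, n = 2), Egfl7 had 26.8% ± 0.124 and Plvap had 25.6% ± 0.497. The strongest peak was centred in an intron of Eng itself, but in an intron of Gm20532 for Egfl7 and of Gtpbp3 for Plvap. For Pecam1 it lay in an exon of Ddx5. From its RefSeq start, an alternative chosen after seeing the data, Pecam1 had 12.2% ± 1.12. From the annotated starts Pecam1 had 9.10% ± 1.96, Kdr, a VEGF receptor, had 4.75% ± 0.757 with its strongest peak at its own promoter, and Emcn was the lowest at 1.00% ± 1.02.

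Signalling genes of the Hedgehog, FGF, Wnt, BMP, retinoic acid and Notch pathways had mean percentiles of 82.3 and 81.3 (adjusted p = 7.60e-05 and 9.50e-05, permutation test), with 16 of 40 highly covered. Rara, a retinoic acid receptor, had 51.4% ± 0.637 (SD, n = 2), Smad7 had 44.9% ± 3.09 and Notch1 had 44.3% ± 1.81. Hox genes of paralogue groups 1 to 6 had the highest mean percentiles, 86.1 and 86.2 (permutation adjusted p = 7.60e-05 and 9.50e-05), and 12 of 18 were highly covered, led by Hoxa5 at 28.4% ± 0.461, Hoxa4 at 27.4% ± 0.534 and Hoxa3 at 27.1% ± 0.475. Their windows overlap, and with 1 member per 200 kb the 4 remaining genes did not pass (higher permutation adjusted p = 0.0740). Signalling genes had a higher mean percentile than these Hox genes with a window of 10 kb, 87.99 against 80.09. The same held with 1 member per 200 kb, 81.78 against 80.39. Groups 9 to 13 had mean percentiles of 66.3 and 68.0 (permutation adjusted p = 0.0366 and 0.0226) with 1 of 16 highly covered, Hoxa9 at 22.4% ± 0.800, followed by Hoxa10 at 14.8% ± 0.283 and Hoxa11 at 13.6% ± 0.454. That call was lost in 7 of the 13 other settings, among them no matching, a window of 10 kb, a window of 100 kb and 1 member per 200 kb (higher permutation adjusted p = 0.0583, 0.373, 0.0509 and 0.886) and matching on the number of TSSs in the window (0.887). The strongest peak in the Hoxa9 window lay 46684 bp downstream of its TSS, in an intron of Hoxa3. It was also the strongest in the windows of Hoxa3, Hoxa4 and Hoxa5, so windows overlap between the 2 lists as well. The 2 Hox lists differed by 19.9 percentile points in replicate 1 and 18.2 in replicate 2 (p = 0.00844 and 0.0141, permutation test, not adjusted). That test treats genes of the same cluster as independent: with 1 member per 200 kb, added after seeing the data, 4 genes of each list remained and differed by 23.8 and 19.98 points (exact p = 0.257 and 0.286, where 0.0286 is the smallest that 70 splits allow).

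Housekeeping genes also ranked higher, at 66.8 and 68.8 (adjusted p = 0.0251 and 0.0103, permutation test), with Rplp0 at 31.7% ± 2.58 (SD, n = 2), Rps18 at 17.7% ± 0.0587, Rpl13a at 17.2% ± 1.81 and Actb at 16.2% ± 1.19. Their call was lost when matched on the number of TSSs in the window and with a window of 100 kb (higher permutation adjusted p = 0.0503 and 0.0509). Olfactory and vomeronasal receptor genes ranked lower, at 11.4 and 11.6 (permutation adjusted p = 7.60e-05 and 9.50e-05), and 1303 of the 1462 were uncovered. The highest of them were Olfr70 at 11.6% ± 0.455, Olfr71 at 10.4% ± 1.02 and Olfr1392 at 8.31% ± 0.492.

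**Figure D4:**
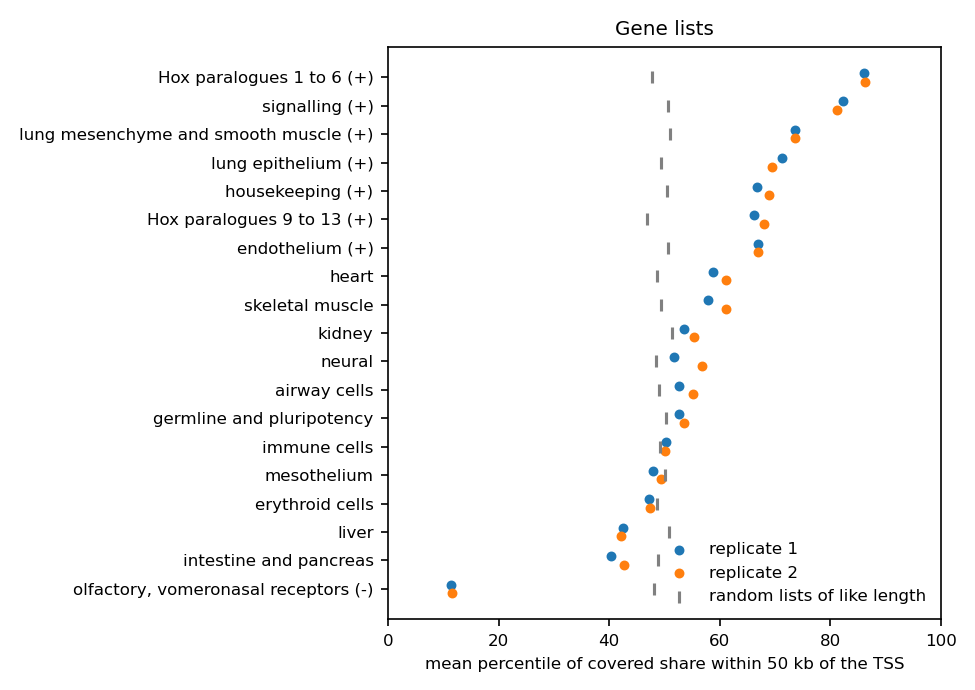
Mean percentile among protein-coding genes of the covered share within 50 kb of the TSS (x axis) for each of the 19 gene lists (y axis). Dots are the replicates, grey bars the mean of random lists of like gene length, and + and - mark the 7 lists called higher and the 1 called lower.

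Other lists were not called in both replicates. Heart genes had mean percentiles of 58.7 and 61.2, with Tnni3 at 12.9% ± 1.82 (SD, n = 2), Myh6 at 10.2% ± 0.0148, Tnnt2 at 9.92% ± 0.436 and Nkx2-5 at 8.29% ± 1.23. Skeletal muscle genes had 57.9 and 61.1, with Tnnt3 at 34.8% ± 0.516 and Tnni2 at 24.4% ± 0.509, whose strongest peak for both lay in an intron of Lsp1, Mymk at 22.9% ± 0.124 and Myod1 at 2.07% ± 0.235. Kidney genes had 53.5 and 55.4, with Slc12a3 at 10.8% ± 2.36, Hnf1b at 9.96% ± 1.65 and Pax2 at 9.94% ± 0.984. Neural genes had 51.7 and 56.8, with Neurod2 at 17.4% ± 0.0672, Lmx1b at 9.94% ± 1.00, Lhx6 at 9.34% ± 1.69 and Neurod1 at 1.06% ± 0.356. With a window of 10 kb the neural list passed, at a mean percentile of 71.45 (higher permutation adjusted p = 7.06e-04). Germline and pluripotency genes had 52.6 and 53.5, with Prm1 at 17.6% ± 1.93, Prm2 at 14.6% ± 1.07, Tdrd1 at 13.4% ± 0.551 and Pou5f1 at 7.73% ± 0.890. Liver genes had 42.5 and 42.2, with Apoa2 at 15.3% ± 0.807, Hpx at 13.9% ± 0.590, Foxa3 at 12.04% ± 0.418 and Alb at 0.955% ± 0.397, and passed as lower only with a window of 10 kb (mean percentile 29.8, higher permutation adjusted p = 0.00318). Intestine and pancreas genes had 40.4 and 42.7, with Cdx1 at 19.7% ± 0.281, Barx1 at 8.46% ± 0.343, Vil1 at 7.34% ± 0.0113 and Cdx2 at 3.57% ± 0.245. The strongest peak in the Cdx1 window lay in an intron of Pdgfrb.

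The lists of airway, immune, mesothelial and erythroid genes were not called either. Airway ciliated, secretory, basal and neuroendocrine genes had mean percentiles of 52.6 and 55.2. Among them Notch2 had 41.9% ± 2.91 (SD, n = 2), Hes1 25.3% ± 2.65, Scgb1a1, the club cell secretoglobin, 13.5% ± 2.00, Foxj1, the ciliated cell factor, 8.91% ± 1.22, Ascl1, of neuroendocrine cells, 2.39% ± 0.461 and Trp63, of basal cells, 0.767% ± 0.0700, and Krt5 had no peak in either replicate. The strongest peak in the Scgb1a1 window lay 16929 bp from its TSS, in an intron of Ahnak. Immune genes had 50.3 and 50.02, with Fcer1g at 16.7% ± 1.33, Cd68 at 15.3% ± 1.20, Aif1 at 10.7% ± 0.547 and Ptprc at 0.298% ± 0.422. The strongest peaks in the windows of Fcer1g, Cd68 and Aif1 lay in other genes, Ndufs2, Tnfsfm13 and Bag6. The Ndufs2 peak was also the strongest in the window of the liver gene Apoa2. Mesothelial genes had 47.9 and 49.4, with Msln at 12.8% ± 0.0148, Upk3b at 8.12% ± 1.67, Aldh1a2 at 7.67% ± 0.551 and Wt1 at 4.53% ± 1.09, and Gpm6a had no peak in either replicate, although from its RefSeq start it had 1.16% ± 0.0990. Erythroid genes had 47.3 and 47.5, with Epor at 14.2% ± 0.988, Slc4a1 at 11.8% ± 0.0106, Tfrc at 10.2% ± 3.44 and the X-linked Gata1 at 0.0995% ± 0.141.

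Tested directly, in pairs chosen after the data were seen, 9 of the 18 differences between the 3 lung lists and 6 other-organ lists passed in both replicates (adjusted p below 0.05, permutation test). All 3 lung lists ranked above liver and above intestine and pancreas, by 24.6 to 32.1 percentile points. Lung epithelium and lung mesenchyme also ranked above neural genes, by 16.1 and 19.4 points, and lung mesenchyme above kidney genes, by 19.2 points. These differences were not matched on gene length or the number of TSSs. Random lists matched on both (added) had an expected mean percentile of 38.2 for neural genes, 44.5 for lung epithelium and 47.5 for lung mesenchyme. Part of the differences from neural genes may thus go with these properties. No difference from heart or skeletal muscle genes passed in both replicates. With a window of 10 kb, added after seeing the data, the differences from neural genes fell to 3.35 and 8.16 points and did not pass (higher permutation adjusted p = 0.968 and 0.277), and that of endothelium from intestine and pancreas did not pass either (0.0609). That of endothelium from neural genes turned from 12.7 to -7.15 points and passed in both replicates with neither window (higher permutation adjusted p with 10 kb = 0.444), but with 100 kb, also added, it was 19.04 points and passed (0.0115). With the window of 10 kb, lung mesenchyme ranked above heart and skeletal muscle genes, by 26.0 and 20.4 points (higher permutation adjusted p = 0.00129 and 0.00909). Lung epithelium ranked above heart and kidney genes with 10 kb, by 21.2 and 23.4 points (higher permutation adjusted p = 0.0142 and 0.0119). None of these differences passed with 100 kb (higher permutation adjusted p = 0.149, 0.363, 0.469 and 0.151).

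Genome-wide, Col4a1, a basement membrane collagen gene on chromosome 8, had the highest covered share, 53.8% ± 3.74 (SD, n = 2), with 56 replicated peaks in its window. Rara followed at 51.4% ± 0.637, then Ncor2 at 49.99% ± 0.349, G430095P16Rik beside Nfix at 48.5% ± 1.71, Gse1 at 48.5% ± 1.46, Ski at 47.8% ± 3.61, Bahcc1 at 45.9% ± 1.75, Smad7 at 44.9% ± 3.09, Smad3 at 44.8% ± 0.1004 and Fzr1 at 44.5% ± 1.19. Ski, Smad3 and Smad7 act in TGF-beta signalling.

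The fourth comparison was between chromosomes. The X chromosome had 0.250% ± 0.0320 of its length under peaks (SD, n = 2). The autosomes ranged from 2.57% ± 0.323 on chromosome 3 to 5.64% ± 0.413 on chromosome 11. The ratio of X to the autosomes was 0.0707 ± 0.00259, a 14.1-fold difference.

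**Figure D5:**
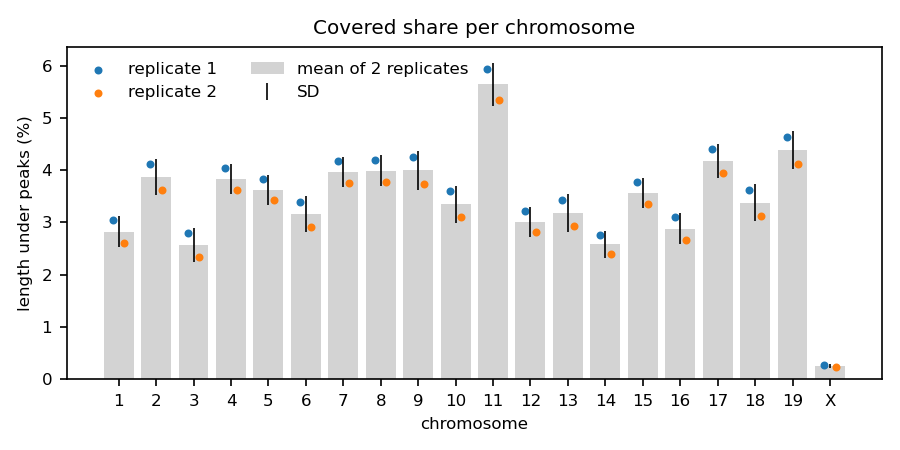
Share of each chromosome's length under peaks (y axis, %, from 0) by chromosome (x axis). Bars are the mean of the 2 replicates, lines the SD and dots the replicates; X, at 0.250%, lies below all 19 autosomes.

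The fifth comparison counted transcription factor motifs in peaks against GC-matched sequence outside peaks. Of 10 motifs 8 were denser in the peaks. The forkhead motif had the largest excess, 1.38 ± 0.0295 (SD, n = 2), above 1 on all 19 autosomes, followed by the E-box at 1.24 ± 0.00579, ETS at 1.16 ± 0.0281, NKX2-1 at 1.16 ± 0.00125, GATA at 1.16 ± 0.0136, AP-1 at 1.15 ± 0.000756, TEAD at 1.12 ± 0.0201 and SOX at 1.04 ± 0.00168. The HOX/TALE motif was at 0.932 ± 0.0124 and the CTCF core, the control, at 0.551 ± 0.0196. Against shuffled peaks forkhead was at 2.08 and GATA at 1.31. The direction turned for 3 motifs: NKX2-1 was at 0.689 and AP-1 at 0.929, and the CTCF core, the control, was at 1.90, second to forkhead. HOX/TALE was at 0.560, below 1 against both backgrounds. Masked repeats made up 13.2% of peak bases and 29.4% of the background, and outside them, a setting chosen after seeing the data, the ratio in the replicated list was 1.03 for AP-1 and 1.01 for SOX. In that setting NKX2-1 was at 1.09, the E-box at 1.15, ETS at 1.25 and forkhead at 1.44. The CTCF core was at 0.790, against 0.534 in the same list with repeats kept, so part of its deficit may go with repeats.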

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

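The test of shared peaks by fold and the test of list ranks between the replicates were chosen after the data were seen.

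Some deposited peaks lie outside the main comparisons. The pooled list has 1 peak on an unplaced X scaffold, with a fold of 2.335 by the authors' value, and the list of replicate 2 has 1 at the same place, with 2.739. The pooled list also holds 19722 peaks, 9.85% of it, that neither replicate's own list touches, with a median fold of 2.21 against 2.63 for the whole list. Of these, 798 are in the replicated list and so entered the comparisons.

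The X chromosome carried far fewer peaks than any autosome. Gene density and repeats do not account for all of it: windows of X genes had 0.127 ± 0.00880 of the coverage of autosomal genes matched on the number of TSSs and on masked sequence (921 of 948 X genes, n = 2), where at least 0.5 had been set as the bound. Without matching the ratio was 0.0817 ± 0.00661, so part of the drop goes with these properties. The X peaks that remain were narrower, with a median width 0.821 ± 0.00698 of the autosomal one. This also argues against removal of X regions regardless of width from otherwise complete lists. That narrowing is what a weaker signal along the whole chromosome predicts. Removal that fell more on wide regions would leave it too, so width cannot tell these apart. X peaks had a median fold of 2.88 against 2.97 on autosomes in replicate 1, and 2.67 against 2.815 in replicate 2. Fewer active X copies in these mixed-sex pools may contribute, but the size of the drop was not tested because the lists hold no reads. How the peak caller and its control treat X against the autosomes stays open as well, and no group in the design varies X copy number.

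Many peaks of 1 replicate were not shared by the other. The 10% of peaks with the highest fold were shared 2.53 ± 0.300 times as often as the 10% with the lowest, which restates the rise already reported and decides nothing about weak peaks near the threshold, so that explanation stays open. Unshared peaks lay within 1 kb of a peak of the other replicate 5.30 ± 0.0997 times as often as after 20 random shifts (66.3% and 70.6% of them). Of the unshared peaks, 24.2% in replicate 1 and 29.1% in replicate 2 touched the other list and so counted by definition. Shifts along whole chromosomes also misalign the regions where both lists cluster, so the ratio cannot tell broken edges from such clustering. Broken or shifted edges of common regions stay a candidate explanation for part of the unshared peaks. Replicate 1 had 1 control alignment and replicate 2 had 2, which cannot be separated from the replicates themselves. No biological explanation was tested, since both replicates belong to 1 group.

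Neural genes ranked 5.17 percentile points higher in replicate 2 than in replicate 1, in 24 of 28 genes (permutation adjusted p = 3.80e-04 over the 19 lists). No other list passed. Skeletal muscle genes rose by 3.19 points and lung epithelium genes changed by -1.905 (permutation adjusted p = 0.0551 for each). Airway, heart, and intestine and pancreas genes rose by 2.62, 2.48 and 2.35 points (permutation adjusted p = 0.135, 0.148 and 0.148). A rise in replicate 2 may thus not be particular to neural genes. CpG content of the neural genes' promoters is argued against as the whole cause of their shift: with random lists matched on CpG ratio and gene length the permutation p was 2.00e-05, the smallest the permutations can give, and the excess was 4.69 points against 4.88 with length alone. Differences in the 2 controls or in the tissue taken into each pool may remain, and neither was tested.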

How the results depend on the processing

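Of 415 recomputed values, 319 stayed on the same side of their threshold or within the spread between replicates, 61 moved, 15 lost a call, 8 gained one and 12, none of them called in either setting, turned direction; the settings named as added were chosen after seeing the data, and the cause of a change was not tested unless stated. Shared peaks of replicate 1 and replicate 2 were 63.6% and 73.55% with any overlap, 36.7% and 41.9% with reciprocal overlap, 48.8% and 63.3% with a −log10 q of at least 5 in both lists, 48.85% and 58.8% in the stronger 50% of both, and 82.0% and 90.6% with that q against the whole other list (added). The ratio of X to autosomes was 0.0583 in the stronger 50% of peaks and 0.0976 in regions per Mb. The promoter excess was 5.39 in the pooled list, 6.43 in the stronger 50% of replicated peaks, 6.37 by summits, and 5.33 to 5.89 with 1 replicate left out. The TSS ratio was 1.98 at 1 kb (added). With a window of 10 kb, endothelium (mean percentile 64.3) and Hox groups 9 to 13 (57.5) lost their calls, neural (71.45) and liver (29.8) gained them, and 2 lists were called lower. With 100 kb, housekeeping (65.8) and Hox groups 9 to 13 (66.2) lost theirs. Matching on the number of TSSs ended the calls of housekeeping (67.8) and Hox groups 9 to 13 (67.1); the latter, at the same mean of 67.1, was also lost without matching and with both properties matched (added), and at 65.7 among autosomal genes (added). Neural, at 54.25, passed with both properties matched (added). With 1 member per 200 kb, which leaves 4 genes in each, Hox groups 1 to 6 (80.4) and 9 to 13 (58.5) lost their calls, and the difference between them was 21.89 points and no longer passed (added). Of the 18 differences between lung and other-organ lists, 10 passed with 10 kb and 10 with 100 kb (both added), and of the 9 that passed with 50 kb, 6 and 9 passed there. The values that turned direction against random lists were immune cells with 10 kb (37.8), matched on the number of TSSs (50.15) or on both properties (50.15, added) and among autosomal genes (48.2, added), erythroid cells with 100 kb (55.9), with 1 member per 200 kb (50.95) and among autosomal genes (52.9, added), neural with 100 kb (46.55), kidney (51.4) and germline genes (37.7) with 10 kb, and mesothelium with RefSeq starts (50.8, added). The difference of endothelium from neural genes turned to -7.15 with 10 kb and passed at 19.04 with 100 kb (both added). The calls of lung epithelium, lung mesenchyme, signalling and receptor genes held in every setting run. Gene starts from RefSeq (added) changed no call. Of the 50 values for single motifs 37 moved by more than the small spread between replicates, and in each of these settings 8 of the 10 motifs stayed denser than in GC-matched sequence, but against shuffled peaks the direction turned for 3. No paired analysis was possible because the design has 1 group. Depth limits none of these values in a way that can be measured here, because no read counts were used.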

Other observations

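The test on CpG content below, the gene families and the X-linked genes were all chosen after seeing the data.

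Gene families sharing the start of their symbol showed wide differences. Of 100 families with at least 20 genes, 24 ranked higher and 21 lower than random lists of like gene length in both replicates (permutation test, adjusted p below 0.05). Histone genes (Hist) were highest, with a mean percentile of 76.4 over 67 genes, though these lie at only 7 separate loci. Semaphorins (Sema) had 72.2 over 20 genes at 19 loci, tetraspanins (Tspan) 71.7 over 20 genes, and mitochondrial ribosomal proteins (Mrpl) 66.3 over 49 genes at 49 loci. At the low end, all 34 X-linked Rhox homeobox genes and all 22 alpha-defensins (Defa) were uncovered, as were 25 of 26 prolactin family genes (Prl), 21 of 22 beta-protocadherins (Pcdhb) and 29 of 34 secretoglobins (Scgb), the family of the covered Scgb1a1. These families are clustered too, at 5, 4, 7, 2 and 15 separate loci in that order, so their genes are not independent. The strongest peak in the Scgb1a1 window lay in an intron of Ahnak, so its coverage need not belong to the secretoglobin gene.

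Among X-linked genes, Bcor, a transcriptional corepressor, had the highest covered share, 14.9% ± 0.902 (SD, n = 2), at percentiles 89.0 and 88.85. Pja1 had 7.71% ± 0.855, Bgn, a matrix proteoglycan whose peaks also lie in the windows of Haus7 and Atp2b3, 7.42% ± 0.173, Efnb1 6.10% ± 0.498 and Gpc3, a glypican of Hedgehog and growth signalling, 5.43% ± 1.06.

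A hypothesis was that the dip at the TSS belongs to CpG-rich promoters. For 9729 CpG-rich TSSs the ratio of coverage 2 kb away to coverage at the TSS was 2.32 ± 0.577 (n = 2), and for the 11999 others it was 0.495 ± 0.0441. Coverage at the TSS was 9.45% ± 1.51 and 13.7% ± 0.483, and 1 kb downstream it was 50.03% ± 2.55 and 14.4% ± 0.507. The dip may thus be a property of CpG-rich promoters, and whether another mark replaces H3K4me1 there was not measured.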
